A study of Mus musculus with 6 samples.

How the data were processed

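The data are polyA RNA-seq libraries of mouse marrow cultures, 3 at 2 kPa and 3 at 50 kPa. Per the labels, femur and tibia marrow of C57BL/6J mice was plated with GM-CSF at 20 ng/ml, given fresh cytokine on days 3, 6 and 10, and RNA was made into libraries with a directional NEBNext Ultra II kit. The deposited values are whole-number read counts per gene symbol, in a table for each library. Per the submitters' processing notes, FastQC 0.11.2, TopHat2 2.0.11, HTSeq 0.6.1p2 and edgeR versions 3.16.5 and 3.8.6 were used, and the builds mm10 and hg19 are named. The notes give no role or order for these tools, and the annotation and the strand setting of the counting are not given in the sources used here. The symbols are those of mouse genes. The tables hold no row of unassigned reads and no mitochondrially encoded gene, so these shares were not analysed here. 6148 genes had 0 counts in all libraries. Counts that could be split between near-identical genes, such as those of the H2 and Mx families, depend on how the authors treated reads with several matches, which is not given in the sources used here.

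Samples were grouped by the stiffness in their titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with too few counts were left out with edgeR's filterByExpr defaults (minimum count 10, minimum total 15), libraries were scaled with TMM factors, and glmQLFit and glmQLFTest were run on a model with stiffness as the term. P-values were adjusted by Benjamini-Hochberg over all 13155 genes tested, and an adjusted p under 0.05 was called. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F value. Normalised CPM used the TMM-scaled library sizes. The common biological coefficient of variation was 24.6%. Libraries held 33.8 M to 36.3 M counts, with TMM factors of 0.927 to 1.16. A level of 1 CPM is 1 count per M of the library size times its factor. Below it counting error adds to the spread between libraries.

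The gene lists (27 of pathways and 18 of cell type markers), the tests and the rule for genes named in the text were fixed before the data were examined. Each list was tested with limma's camera on log2 CPM (prior count 2) with the preset correlation of 0.01 between genes, 2-sided, with Benjamini-Hochberg adjustment over the 43 lists that had at least 5 tested genes. Camera with a correlation estimated for each list and limma's fry were run beside it. Camera and edgeR counts per list were set beside counts adjusted over the list alone. A list's score in a library is the mean log2 CPM of its tested members in that library minus their mean over the 6 libraries. Named genes were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap, out of 134 and 94 such genes, leaving out predicted genes, pseudogenes and small RNAs. A further 16 genes of stiffness sensing, dendritic cell function and metabolism were reported whatever their result. So were the 4 members with the smallest p of each list that camera called or that had at least 3 members past the threshold, and at most 2 members of each other list. A few genes and 1 list that these rules give are not reported here. Gene symbols were matched to GENCODE vM21 on GRCm38 for coordinates, exon overlap and GC content, 22750 by current and 935 by older symbol, with 377 unmatched.

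Alternatives were edgeR's RLE, upper-quartile and total-count scalings, no low-count filter, a filter of at least 5 CPM in 3 libraries, DESeq2's Wald test, limma-voom, robust quasi-likelihood fits, replicate number as a block, a fold change of at least 2-fold, and leaving out each library in turn. A GC trend removed from each library and the summing of high tension replicates 1 and 2 were added after seeing the data. The labels do not say that a replicate number marks a shared animal or day, so the numbers were not taken as pairs. Deviations from the group mean correlated with r = 0.54, -0.11 and 0.49 over genes for numbers 1, 2 and 3. By these correlations 3 of 6 libraries were closest to the library of their own number, which does not settle whether the numbers mark pairs. The procedure was tested on simulated data for 50 kPa against 2 kPa, with 13155 genes, the spread of these libraries and 200 changed genes. It called 35% of genes changed 2-fold and 96% of genes changed 8-fold, 100% of them in the right direction, and 7 unchanged genes among 139 calls. A raised list had a camera adjusted p of 2.75e-13, and 0.0429 with an estimated correlation, and 0 of 40 unchanged lists were called. Simulated genes were drawn independently of each other. The called lists had estimated correlations of 0.057 to 0.95, so the simulation does not test camera on lists like these. Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6 drew the plots.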

Results

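Mouse bone marrow cells from the C57BL/6J strain were grown with GM-CSF, the cytokine used to drive marrow precursors towards dendritic cells and macrophages, on substrates of 2 stiffnesses. The soft substrate, called low tension, was 2 kPa, close to the stiffness of healthy tissue. The stiff substrate, called high tension, was 50 kPa, a stiffness seen in fibrotic and inflamed tissue. PolyA RNA was sequenced from 3 samples per stiffness, whose titles name dendritic cells. The labels name no sort, so each value is taken as an average over all cell types of the sample. At 2 kPa the totals were 36.3 M, 36.04 M and 35.9 M counts in replicates 1 to 3. At 50 kPa they were 33.8 M, 34.9 M and 36.1 M. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The comparison of the 2 stiffnesses asks how a static mechanical environment alters transcription across the cells of such a culture, and the study's title points to metabolism and dendritic cell function. Log2 fold changes are given as 50 kPa over 2 kPa with their standard errors. Levels are normalised CPM, counts per M of the scaled library, as mean ± SD over n = 3 samples.

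At 50 kPa 10 of 20 neutrophil, 6 of 9 B cell and 4 of 9 megakaryocyte marker genes fell, and Ocstamp, tenascin C and collagenase 3 transcripts rose. The 3 marker lists were called lower as lists by camera, and these calls were lost with a correlation estimated for each list (adjusted p = 0.647 with an estimated correlation for each). S100a9, a calcium-binding protein abundant in neutrophils, was 1676 ± 666 CPM at 2 kPa and 211 ± 86.8 CPM at 50 kPa, a fall of 7.93-fold. Igj, the joining chain of polymeric immunoglobulins, went from 911 ± 258 to 47.3 ± 34.1 CPM, 19.2-fold lower, and 31.3-fold lower without high tension replicate 3. Ocstamp, a transmembrane protein of osteoclast fusion, rose 15.6-fold, from 2.63 ± 1.04 to 40.9 ± 5.53 CPM. Mmp13, which encodes collagenase 3, rose 7.23-fold, from 104 ± 58.8 to 753 ± 79.0 CPM. In each of these 4 genes the levels at 50 kPa did not overlap those at 2 kPa, as in all 454 called genes. Genes of oxidative phosphorylation gave 0 calls by edgeR among 75 tested, beside 454 among all 13155 genes. By edgeR 7 of the 75 had an unadjusted p under 0.05, beside 3660 of the 13155, and DESeq2 called 1 of the 75.

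Of 13155 genes tested with edgeR's quasi-likelihood test, 194 were higher and 260 lower at 50 kPa at a Benjamini-Hochberg adjusted p under 0.05. The called genes had edgeR adjusted p-values from 0.022 to 0.05, and 3660 genes had an unadjusted p under 0.05. DESeq2 called 1121 higher and 1251 lower. All 454 called genes had groups that did not overlap, a property of 34.1% of tested genes against 10% given by chance. A change of at least 2-fold was seen in 97 of the higher and 223 of the lower genes. 214 called genes had a mean level below 5 CPM. With total counts as the scaling, which moved the median log2 fold change of all genes from -0.028 to -0.16, the split was 77 higher and 257 lower. The counts of calls also rested on single libraries: higher and lower genes numbered 1 and 0 without low tension replicate 2, 3 and 0 without low tension replicate 3, 0 and 0 without high tension replicate 1 or replicate 2, and 118 and 215 without high tension replicate 3. In these 5 fits edgeR still gave 2787, 4184, 2080, 2062 and 3892 genes with an unadjusted p under 0.05. All 454 called genes kept their direction and an unadjusted p under 0.05 in each of the 6 fits that left out 1 library. They had been called on these same libraries, so this is not an independent check.

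The first principal component of log2 CPM held 67.9% of the variance and placed every 2 kPa library below every 50 kPa library. High tension replicates 1 and 2 lay at 54.5 and 59.5 on it, low tension replicates 2 and 3 at -57.4 and -51.5. Low tension replicate 1 (-13.1) and high tension replicate 3 (8.06) lay between them. A chi-square per degree of freedom over tested genes is larger the less 2 libraries resemble each other. Low tension replicate 1 gave 126, 136 and 122 with high tension replicates 1, 2 and 3, but 156 and 213 with low tension replicates 2 and 3. Its Pearson correlations of log2 CPM were 0.970, 0.967 and 0.978 with the former and 0.975 and 0.973 with the latter. High tension replicates 1 and 2 resembled each other more than any other pair, with a chi-square of 6.78 per degree of freedom over tested genes, against 127 to 234 for the other pairs within a group. The labels list them as replicates and they were treated so, although these values do not show whether they came from separate cultures. With their counts summed into 1 sample, a choice made after seeing the data, edgeR called 0 genes higher and 0 lower, with 2138 at an unadjusted p under 0.05. The 10 most abundant genes took 8.06 ± 0.879% of counts at 2 kPa and 11.5 ± 1.04% at 50 kPa (SD, n = 3; 2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, adjusted p = 0.25 over 5 library measures).

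**Figure D1:**
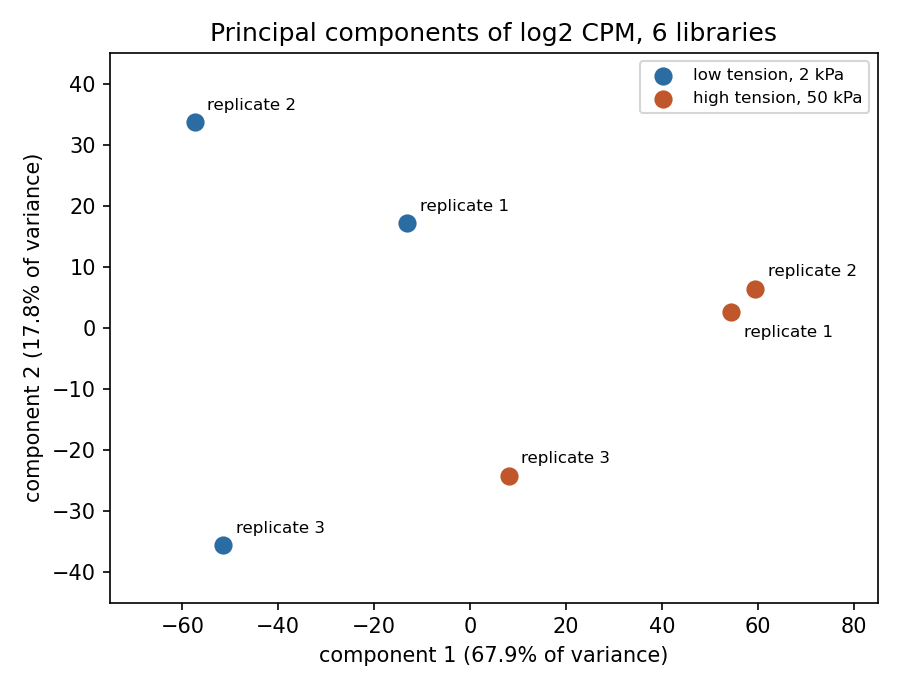
Principal components 1 and 2 of log2 CPM over all tested genes for the 6 libraries, in component units, coloured by stiffness. The 2 kPa libraries lie below 0 and the 50 kPa libraries above 0 on component 1, with high tension replicate 3 at 8.06 and low tension replicate 1 at -13.1.

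The 10 largest rises among genes past the threshold with a mean of at least 5 CPM were led by Ocstamp (3.96 ± 0.33, edgeR adjusted p = 0.0286), which lies at chromosome 2, 165393760 to 165400405, minus strand of GRCm38. Tnc, which encodes the matrix glycoprotein tenascin C (chromosome 4, 63959785 to 64047015, minus strand), rose by 3.64 ± 0.29 from 0.943 ± 0.381 to 11.7 ± 0.867 CPM (edgeR adjusted p = 0.0286). Mmp13 (chromosome 9, 7272514 to 7283331, plus strand) rose by 2.85 ± 0.48 (edgeR adjusted p = 0.0399). Ccdc80 (chromosome 16, 45093402 to 45128077, plus strand) rose by 2.35 ± 0.27 from 14.0 ± 5.28 to 71.0 ± 4.41 CPM (edgeR adjusted p = 0.0291). Ly86, the MD-1 partner of the Toll-like receptor homologue Cd180, rose from 5.78 ± 2.35 to 40.8 ± 10.7 CPM, a log2 change of 2.82 ± 0.38. Rgs16, a GTPase activator that dampens G protein signalling, changed by 2.85 ± 0.46, the orphan receptor gene Gpr162 by 2.53 ± 0.31 and the kinase gene Wnk2 by 2.39 ± 0.40. Mucl1, a small mucin-like gene, rose by 3.37 ± 0.60 and Esyt3, an extended synaptotagmin, by 2.60 ± 0.49. The edgeR adjusted p-values of these last 6 genes lay between 0.0296 and 0.0486. Esyt3 stood at 3.27 without low tension replicate 1 and Rgs16 at 3.47 without low tension replicate 3.

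The 10 largest falls were led by Igj, now named Jchain (chromosome 5, 88519809 to 88527891, minus strand), at -4.27 ± 0.63 (edgeR adjusted p = 0.0357). Several further genes of this set act in B cells and antibody-secreting cells. Pou2af1, a transcriptional coactivator of B cells (chromosome 9, 51213708 to 51240080, plus strand), fell from 32.2 ± 10.6 to 2.27 ± 1.46 CPM, a log2 change of -3.82 ± 0.56 (edgeR adjusted p = 0.0355). Mzb1, an endoplasmic reticulum chaperone of B cells, changed by -3.43 ± 0.46, Cd79a, the signalling chain of the B cell receptor, by -3.36 ± 0.51, and Derl3, a gene of endoplasmic reticulum-associated degradation, by -3.22 ± 0.46. Lax1, an adaptor of lymphocyte signalling, changed by -3.53 ± 0.51. Ltf, the lactoferrin of neutrophil granules (chromosome 9, 111019271 to 111042767, plus strand), fell from 393 ± 88.0 to 40.5 ± 20.3 CPM (-3.28 ± 0.40, edgeR adjusted p = 0.0296). The platelet chemokine gene Ppbp (chromosome 5, 90768518 to 90770063, plus strand) fell from 56.3 ± 10.9 to 6.15 ± 4.09 CPM (-3.19 ± 0.47, edgeR adjusted p = 0.0353). Rab27b, a small GTPase of granule secretion, changed by -3.45 ± 0.60 and Cmah, the hydroxylase that makes N-glycolylneuraminic acid, by -2.99 ± 0.28. The edgeR adjusted p-values of Mzb1, Cd79a, Derl3, Lax1, Rab27b and Cmah lay between 0.0286 and 0.0444. Without high tension replicate 3 Igj, Lax1, Rab27b and Ppbp stood at -4.97, -4.24, -4.44 and -3.88.

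**Figure D2:**
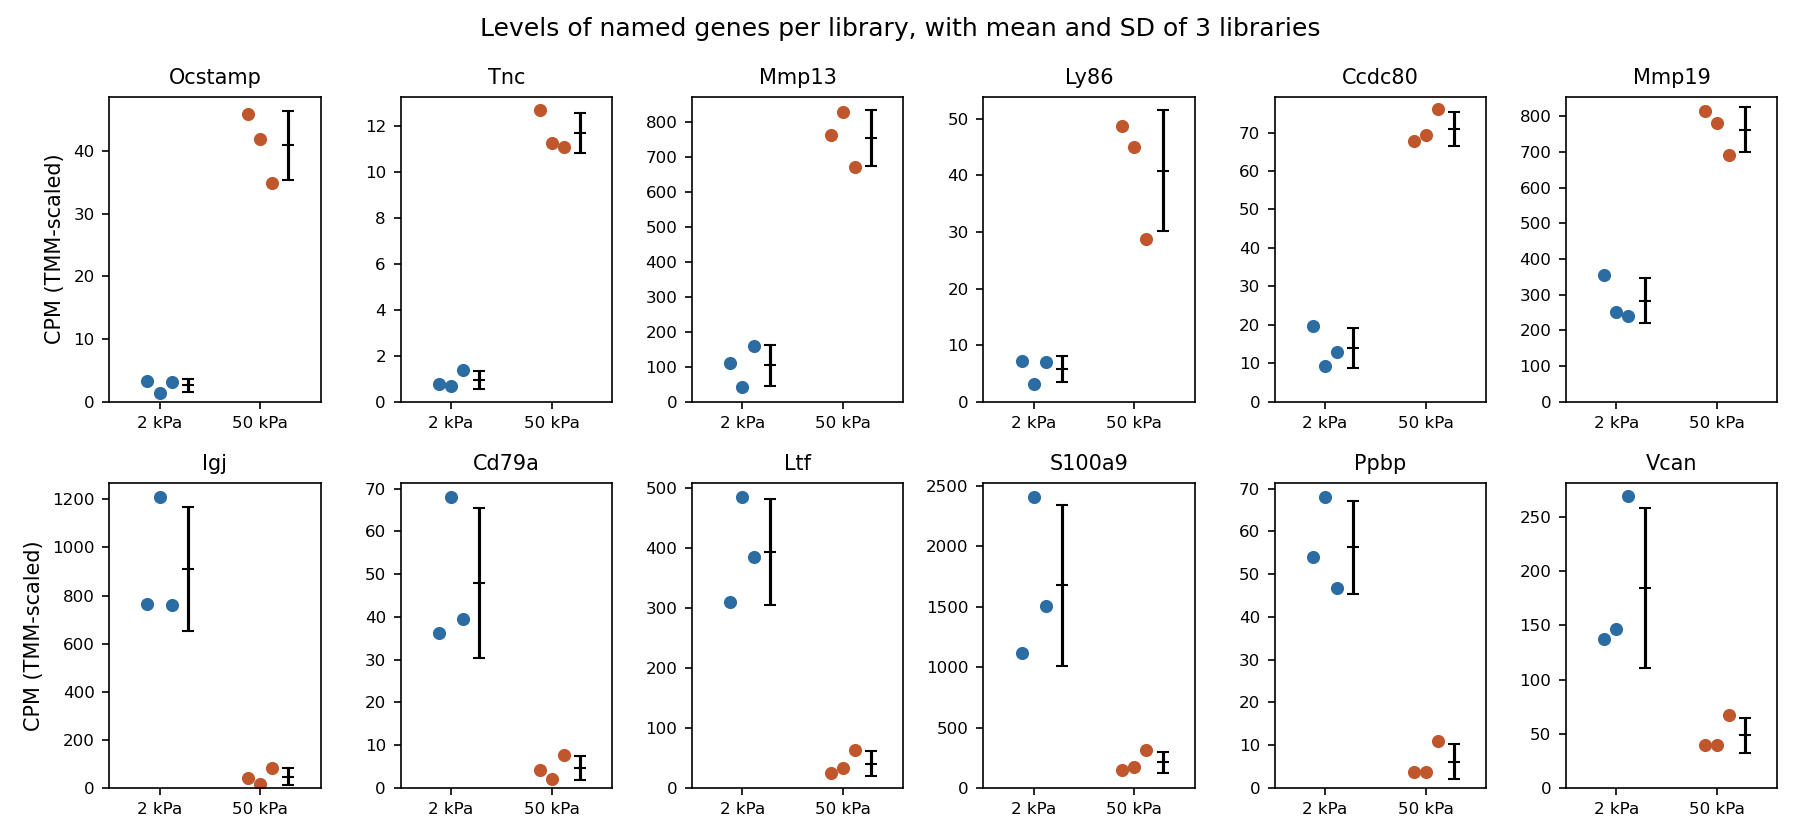
Normalised CPM of 12 genes in each library at 2 kPa (blue) and 50 kPa (orange), with the mean and SD of 3 libraries as a bar. The upper row holds genes that rose and the lower row genes that fell. In each panel the 3 libraries of a stiffness lie apart from those of the other, as in all 454 called genes.

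Of the named genes past the threshold, Tnc, Rgs16, Esyt3, Foxf2, Mmp19 and Cox6a2 share exon sequence with a gene on the opposite strand in the annotation, as do 31 of the 152 genes named by the rule in all. The library kit was directional, but the strand setting of the counting is not given in the sources used here, so the values of these genes may hold reads of both strands.

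Several lists of markers of cell types other than dendritic cells and macrophages were called lower at 50 kPa by camera, each with its p at an estimated correlation beside it. Each list was tested against all other genes with camera. Ranges of camera adjusted p-values given for a list span 10 other fits, or 9 where a filter left too few genes, with another scaling, a stricter filter, replicate number as a block or 1 library fewer. Of 20 neutrophil markers tested, 10 fell, 0 rose and 10 were not called, and 18 were lower when adjusted over the list alone. Ltf, Pglyrp1 (-2.50 ± 0.30), a peptidoglycan recognition protein, Camp (-2.95 ± 0.37), the cathelicidin precursor, and S100a9 (-2.99 ± 0.42) had the smallest p-values. The list's median log2 fold change was -2.25 (camera adjusted p = 1.86e-10; adjusted p = 0.647 with an estimated correlation). B cell markers fell in 6 of 9 genes, with 0 higher and 9 lower when adjusted over the list alone. Cd79b, Ms4a1, Cd79a and Ebf1 changed by -2.81 ± 0.33, -3.16 ± 0.42, -3.36 ± 0.51 and -2.46 ± 0.40, and the list's median was -2.46 (camera adjusted p = 1.80e-06; adjusted p = 0.647 with an estimated correlation). Megakaryocyte markers fell in 4 of 9 genes, with 0 higher and 7 lower when adjusted over the list alone. These were the platelet glycoprotein genes Gp9 (-3.92 ± 0.42) and Gp1ba (-3.26 ± 0.38), Ppbp and the integrin gene Itga2b (-2.51 ± 0.44), at -3.12 without high tension replicate 3. The list's median was -3.19 (camera adjusted p = 4.29e-05; adjusted p = 0.647 with an estimated correlation).

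Monocyte markers fell in 3 of 10 genes, 0 rose, and over the list alone 4 were lower and 1 higher. Cd177 (-2.86 ± 0.42) and Vcan, which encodes versican (-1.93 ± 0.35), were among those that fell, while Fcnb was at -2.20 ± 0.57 (edgeR adjusted p = 0.081), and at -2.90 without high tension replicate 3. Cd177 is not particular to monocytes, and the neutrophil marker median on these libraries was -2.25. The gene higher over the list alone, named after its values were seen, was the coagulation factor gene F13a1 (0.86 ± 0.22). The median was -1.29 (camera adjusted p = 0.0086; adjusted p = 0.647 with an estimated correlation), and -2.74 without high tension replicate 3. Among 13 basophil and mast cell markers 1 fell, the transcription factor gene Gata1 (-2.72 ± 0.48), and 10 were lower when adjusted over the list alone. Prss34, Fcer1a and Cpa3 stood at -4.00 ± 0.94, -3.98 ± 0.95 and -2.18 ± 0.53, with edgeR adjusted p-values of 0.0683, 0.0698 and 0.0735. Prss34 and Fcer1a were highest in low tension replicate 2 and stood at -2.91 and -3.03 without it. Prss34, Fcer1a and Cpa3 were at -5.04, -5.53 and -2.88 without high tension replicate 3. The list's median was -2.19 (camera adjusted p = 1.66e-05; adjusted p = 0.647 with an estimated correlation). Promyelocyte markers gave 0 calls among 11 genes and 7 lower genes when adjusted over the list alone. Their median was -2.54 (camera adjusted p = 0.0196; adjusted p = 0.647 with an estimated correlation; camera adjusted p = 0.097 without low tension replicate 3 and 0.0539 with replicate number as a block, range 0.00938 to 0.097). Their smallest p-values belonged to Myb (-2.85 ± 0.73), the azurophil granule genes Prtn3 (-3.60 ± 0.97) and Ctsg (-2.98 ± 0.91), and Ms4a3 (-2.54 ± 0.73). These 4 genes were highest in low tension replicate 2, and without it they stood at -1.82, -2.22, -1.78 and -1.40 and the list's median at -1.40. Without high tension replicate 3 Prtn3 and Ctsg stood at -4.46 and -3.83. Fibroblast and stromal markers gave 0 calls among 12 genes and 2 lower genes when adjusted over the list alone. Their median was -1.24 (camera adjusted p = 0.00752; adjusted p = 0.647 with an estimated correlation). Lum, Col3a1, Cxcl12 and Dcn of this list stood at -4.36 ± 1.13, -3.31 ± 0.86, -2.25 ± 0.70 and -2.42 ± 0.78, each below 4 CPM in both groups. Without low tension replicate 2 Lum and Col3a1 stood at -2.99 and -2.17, and without high tension replicate 3 Lum, Cxcl12 and Dcn at -5.00, -3.43 and -3.50. This list's camera adjusted p was 0.0738 without low tension replicate 2, 0.127 without low tension replicate 3 and 0.0775 without high tension replicate 3, where the median was -0.83 (range 0.00201 to 0.127). At an unadjusted p under 0.05 edgeR gave 7 promyelocyte and 5 stromal markers, and DESeq2 called 7 and 4.

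Among markers of the cells that GM-CSF favours, those of macrophages had a positive median and those of GM-CSF dendritic cells a negative one. None of 16 macrophage markers passed the gene-level test, 13 had a positive fold change, and the median was 0.94 (camera adjusted p = 0.000966; adjusted p = 0.647 with an estimated correlation), with 0 calls when adjusted over the list alone. By edgeR 8 of them had an unadjusted p under 0.05, all higher, and DESeq2 called 4. The median was 1.59 without low tension replicate 1 and 0.60 without low tension replicate 2. Apoe, which encodes apolipoprotein E, stood at 1.94 ± 0.45 (edgeR adjusted p = 0.0675). The haemoglobin scavenger receptor gene Cd163, below 1 CPM in both groups, stood at 1.41 ± 0.44 and the complement gene C1qa at 1.39 ± 0.48. Of 14 GM-CSF dendritic cell markers, Adam23 (-1.02 ± 0.17) and Cd226 (-2.28 ± 0.43) fell, 0 rose, and 7 were lower when adjusted over the list alone. Dpp4 (-1.41 ± 0.28) and Cd24a (-0.74 ± 0.16) had edgeR adjusted p-values of 0.0527 and 0.0618. The median was -0.55 (camera adjusted p = 0.0138; adjusted p = 0.647 with an estimated correlation; camera adjusted p = 0.088 without low tension replicate 3, range 0.00232 to 0.088). Itgax, the gene of the dendritic cell and macrophage integrin CD11c, was 801 ± 439 CPM at 2 kPa and 2399 ± 857 CPM at 50 kPa (1.58 ± 0.54, edgeR adjusted p = 0.13).

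The remaining cell type lists were not called by camera. At the gene level Cd4 (0.473 ± 0.119 to 3.60 ± 1.02 CPM, 2.93 ± 0.32) rose among 12 T and NK cell markers. Ly6d (-2.89 ± 0.41) fell and Cox6a2 (0.218 ± 0.103 to 1.04 ± 0.0712 CPM, 2.23 ± 0.35) rose among 9 plasmacytoid dendritic cell markers. Ocstamp rose and Itgb3 (-0.91 ± 0.15) fell among 10 osteoclast markers. Medians and camera adjusted p-values were -0.62 and 0.619 for T and NK cell, -0.34 and 0.63 for plasmacytoid dendritic cell, and -0.093 and 0.991 for osteoclast markers, whose mean was 0.30. Eosinophil markers (10 tested, median -1.09, camera adjusted p = 0.196), cDC1 markers (10 tested, -0.20, 0.811), cDC2 markers (9 tested, 0.46, 0.275) and endothelial markers (7 tested, -0.24, 0.606) had 0 gene-level calls by edgeR. At an unadjusted p under 0.05 these 4 lists held 7, 5, 2 and 3 genes, and DESeq2 called 5, 3, 1 and 2. Adjusted over the list alone, 5 eosinophil, 2 cDC1, 0 cDC2, 1 endothelial, 1 T and NK cell, 1 plasmacytoid dendritic cell and 3 osteoclast markers were lower, and 1, 1 and 2 of the last 3 lists were higher. The members of these lists with the smallest p that did not pass over all genes were Il5ra (-1.90 ± 0.48), Prg3 (-2.14 ± 0.55), Gcsam (-2.23 ± 0.47), Batf3 (-0.46 ± 0.11), Mgl2 (2.38 ± 0.70), S100a4 (-0.49 ± 0.18), Tie1 (-2.03 ± 0.50), Egfl7 (-1.27 ± 0.39) and Il2rb (-2.11 ± 0.47). The other members lower or higher over the list alone, named after their values were seen, were the eosinophil genes Prg2 (-1.99 ± 0.56), Ccr3 (-1.42 ± 0.43) and Alox15 (-0.77 ± 0.24) and the osteoclast genes Mmp9 (-1.17 ± 0.28), Myo1d (-0.69 ± 0.20) and Dcstamp (1.44 ± 0.34). Prg2 and Prg3 stood at -1.35 and -1.46 without low tension replicate 2, Gcsam at -2.91 without high tension replicate 3 and Mgl2 at 3.11 without low tension replicate 1. Erythroid markers had 0 genes above the filter and adipocyte markers 1, Retn, at -0.90 ± 0.39.

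**Figure D3:**
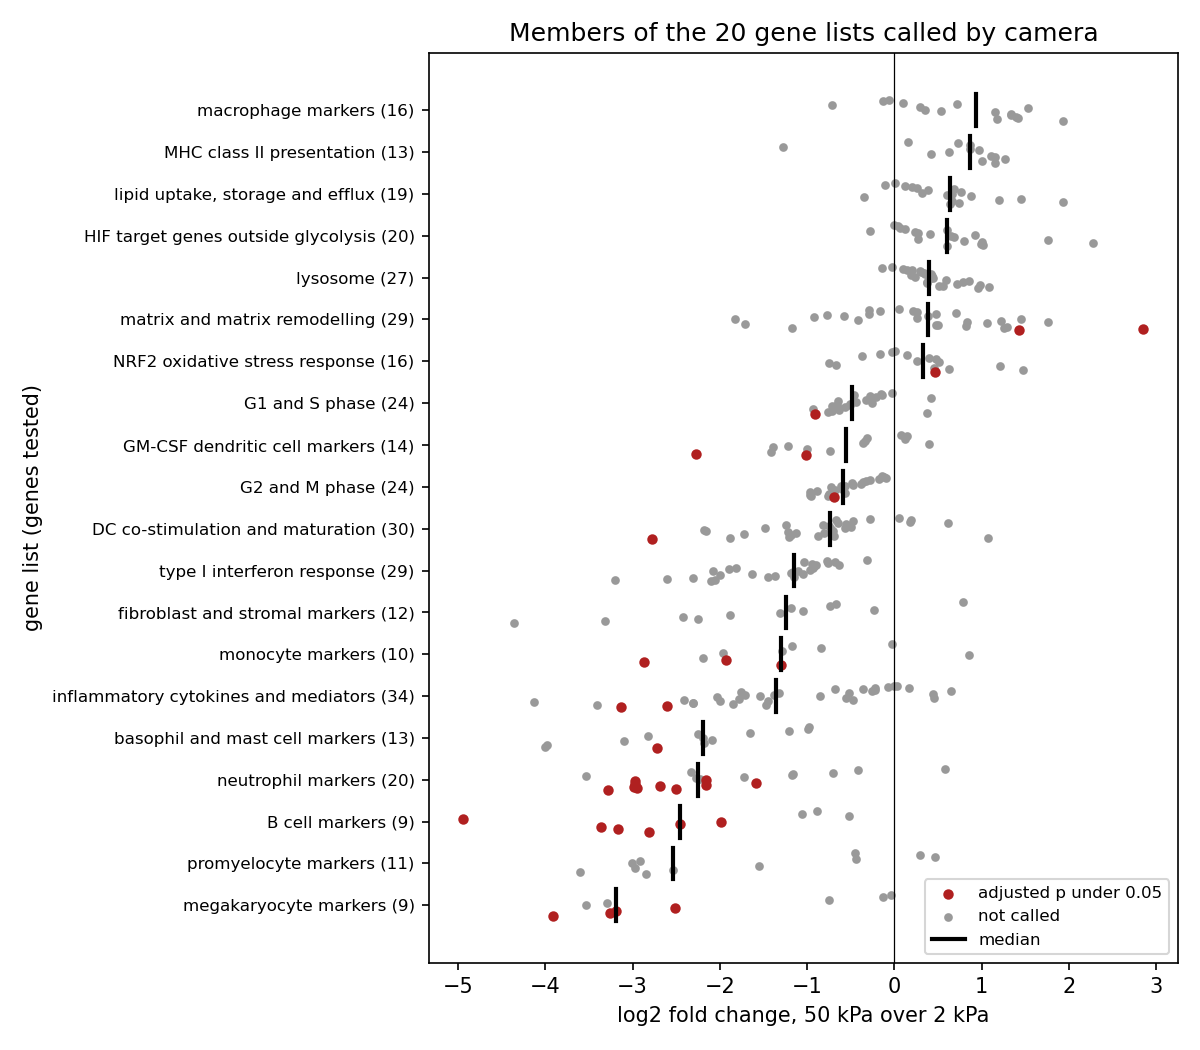
Log2 fold changes (50 kPa over 2 kPa) of every tested member of the 20 lists called by camera, 1 point per gene, with the list median as a black bar and genes past the gene-level threshold in red. Medians run from -3.19 for megakaryocyte to 0.94 for macrophage markers.

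Of 30 dendritic cell co-stimulation and maturation genes 1 fell, Lad1 (-2.78 ± 0.39), 0 rose, and over the list alone 13 were lower and 1 higher. The median was -0.74 (camera lower, adjusted p = 0.000408; adjusted p = 0.739 with an estimated correlation). The list's score was highest in low tension replicate 3 (1.01), and 0.03 in high tension replicate 3 against -0.016 in low tension replicate 1. Without low tension replicate 3 the median was -0.36 and the camera adjusted p 0.0496 (range 5.61e-06 to 0.0496). Fscn1, the actin bundler fascin, stood at -1.88 ± 0.43, Cacnb3 at -1.21 ± 0.28 and the co-stimulatory receptor gene Tnfrsf9 at 1.07 ± 0.24, with edgeR adjusted p-values of 0.0675, 0.0675 and 0.0632. Cd80, Cd86 and Cd40, ligands or receptors that stimulate T cells, were at -0.50 ± 0.23, -1.13 ± 0.34 and -2.19 ± 0.73, with edgeR adjusted p-values of 0.215, 0.103 and 0.124. Cd40 stood at -0.94 without low tension replicate 3. None of 13 MHC class II presentation genes passed over all genes, 10 were higher and 1 lower when adjusted over the list alone, and the median was 0.87 (camera higher, adjusted p = 0.000575; adjusted p = 0.648 with an estimated correlation). By edgeR 11 had an unadjusted p under 0.05, the lower of them H2-Eb2, named after its values were seen, at -1.28 ± 0.48, and DESeq2 called 8. Low tension replicate 2 stood apart, with a score of -0.99 against -0.093 and -0.035 in low tension replicates 1 and 3, and the median without it was 0.60. The score of high tension replicate 3 was 0.13. H2-Ab1 was 1745 ± 668 CPM at 2 kPa and 3867 ± 891 CPM at 50 kPa (1.15 ± 0.36, edgeR adjusted p = 0.114). H2-Aa stood at 1.27 ± 0.39, H2-Ob at 1.00 ± 0.28, and Ifi30, a thiol reductase of antigen processing, at 1.15 ± 0.24. MHC class I presentation gave 0 calls by edgeR among 18 genes, 2 at an unadjusted p under 0.05 and 1 by DESeq2 (median -0.14, mean -0.16, camera direction higher with adjusted p = 0.907), with B2m at 0.65 ± 0.25 and H2-D1 at 0.62 ± 0.25. On the same libraries the macrophage marker median was 0.94 and the neutrophil marker median -2.25.

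Inflammatory cytokines and mediators had a median of -1.35 over 34 genes (camera adjusted p = 0.0026; adjusted p = 0.739 with an estimated correlation), of which 2 fell, 0 rose, and 2 were lower when adjusted over the list alone. Il10, an anti-inflammatory cytokine gene, fell from 3.98 ± 1.83 to 0.449 ± 0.157 CPM (-3.14 ± 0.45). The chemokine gene Ccl24 fell (-2.61 ± 0.43) at under 1 CPM. Il6 stood at -3.40 ± 1.05 (edgeR adjusted p = 0.11), Tnf at -1.45 ± 0.59 (0.175), Il1b at -1.38 ± 0.79 (0.297) and Nfkbiz at -1.47 ± 0.43 (0.0983). Without low tension replicate 3 Il6, Tnf and Il1b stood at -2.56, -0.46 and -0.70, and without high tension replicate 3 Il6 and Il1b at -5.14 and -2.47. All 29 type I interferon response genes had a negative fold change and 0 were called, over all genes or over the list alone, with 0 at an unadjusted p under 0.05 by edgeR and 0 called by DESeq2. Their median was -1.15 (camera adjusted p = 0.000927; adjusted p = 0.739 with an estimated correlation). Mx1, Cmpk2, Mx2 and Rsad2 were at -2.10 ± 0.89, -3.20 ± 1.37, -2.05 ± 1.03 and -2.60 ± 1.42. Without low tension replicate 3 these 4 genes stood at -0.83, -1.40, -0.65 and -0.77, and without high tension replicate 3 at -3.01, -4.96, -3.36 and -4.59. Both lists were highest in low tension replicate 3, with scores of 1.54 and 2.19, and without that library their medians were -0.33 and -0.19 and their camera adjusted p-values 0.52 and 0.137 (ranges 2.79e-05 to 0.52 and 3.94e-14 to 0.137). Without high tension replicate 3 the interferon median was -2.41. Pattern recognition receptors gave 0 calls by edgeR among 34 genes, 2 at an unadjusted p under 0.05 and 2 by DESeq2 (median -0.19, camera adjusted p = 0.628), led by Clec4n at 0.73 ± 0.16 and Myd88 at -0.58 ± 0.18. Monocyte markers, at a median of -1.29, were also highest in low tension replicate 3, with a score of 1.13.

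**Figure D4:**
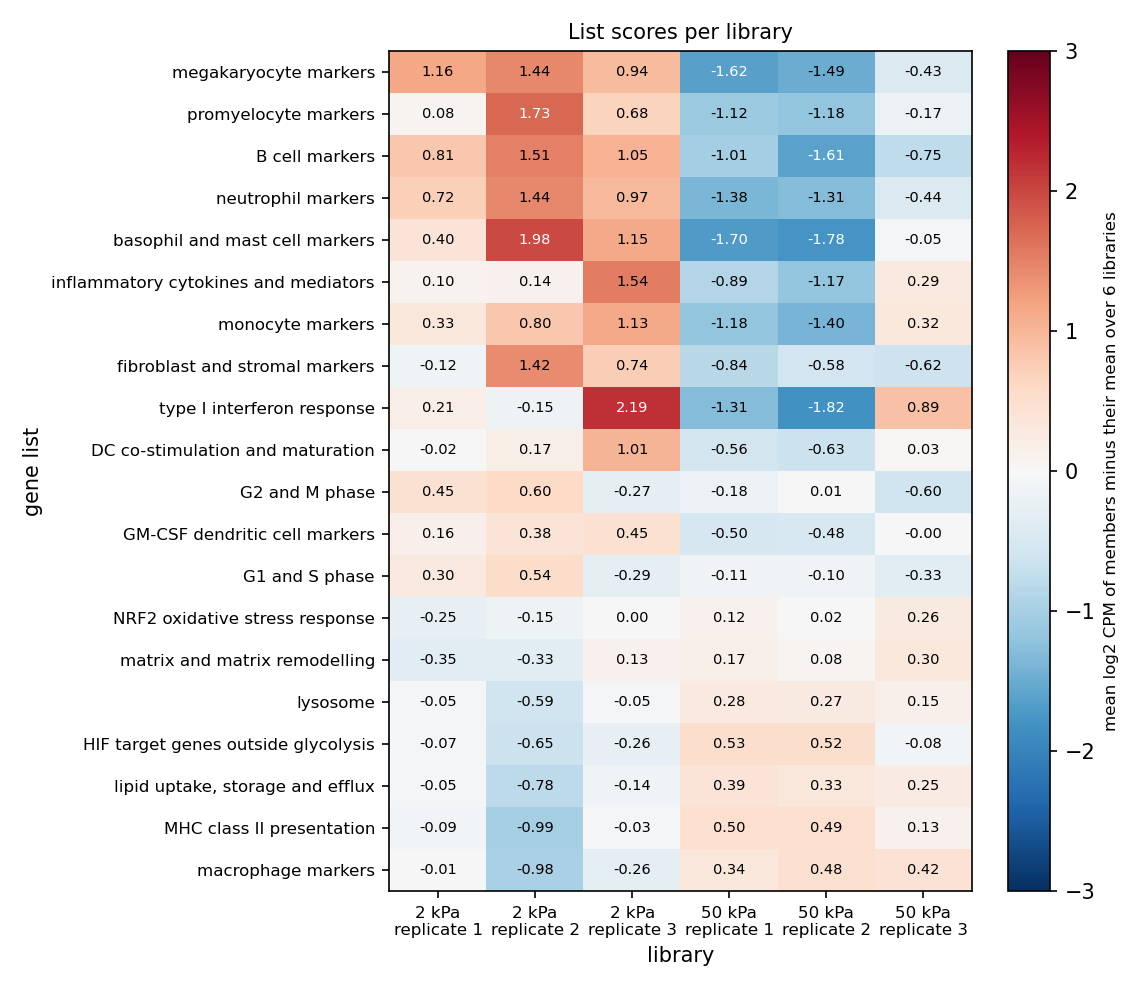
Scores of the 20 lists called by camera in each library, as the mean log2 CPM of the members minus their mean over the 6 libraries, with higher scores in red and lower ones in blue. High tension replicate 3 scores 0.89 for the interferon list against -1.31 and -1.82 in high tension replicates 1 and 2.

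The lists of central carbon metabolism were not called. Glycolysis had 0 calls among 23 genes and a median of 0.10 (camera adjusted p = 0.431). The pentose phosphate pathway had 0 among 7 (-0.12, 0.811), the TCA cycle and pyruvate entry 0 among 20 (0.018, 0.634) and oxidative phosphorylation 0 among 75 (0.0066, mean -0.02, 0.906). Adjusted over the list alone, 1 gene of the TCA list, the pyruvate carboxylase gene Pcx, was higher and 0 genes of the other 3 lists were called. At an unadjusted p under 0.05 edgeR gave 5, 0, 4 and 7 genes of these 4 lists, and DESeq2 called 5, 0, 2 and 1. Slc2a1, the GLUT1 glucose transporter gene, was 265 ± 30.1 CPM at 2 kPa and 386 ± 71.2 CPM at 50 kPa (0.54 ± 0.18, edgeR adjusted p = 0.118). The GLUT3 gene Slc2a3 stood at -0.98 ± 0.26 (edgeR adjusted p = 0.0851). The hexokinase gene Hk2 was at 0.21 ± 0.23, Ldha, the lactate dehydrogenase A gene, at -0.19 ± 0.14 and the aldolase gene Aldoc at 0.55 ± 0.12, with edgeR adjusted p-values of 0.565, 0.405 and 0.0655. Other members with the smallest p were Pcx (0.97 ± 0.20), Suclg2 (-0.68 ± 0.25), Ndufa6 (0.39 ± 0.11), Ndufa4 (-0.56 ± 0.19), Rpia (-0.39 ± 0.22) and Rpe (-0.22 ± 0.16). With total counts as the scaling, the medians of glycolysis, the TCA cycle, oxidative phosphorylation, fatty acid synthesis and fatty acid oxidation turned negative, as the median of all genes moved to -0.16.

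Among lipid genes, the list of lipid uptake, storage and efflux was called higher, with a positive fold change in 17 of 19 genes and a median of 0.64 (camera adjusted p = 0.000646; adjusted p = 0.647 with an estimated correlation). Low tension replicate 2 stood apart here too, with a score of -0.78 against -0.047 and -0.14 in low tension replicates 1 and 3, and the median without it was 0.43. The list held 0 calls over all genes and 4 higher genes when adjusted over the list alone. The scavenger receptor gene Cd36 was 133 ± 17.4 CPM at 2 kPa and 206 ± 10.2 CPM at 50 kPa (0.64 ± 0.13, edgeR adjusted p = 0.0521). Apoe, which is also on the macrophage list, was 134 ± 72.3 and 515 ± 37.5 CPM, and Pltp and Npc1, which move phospholipid and cholesterol, stood at 0.74 ± 0.16 and 0.66 ± 0.16. The lysosome list was called higher with 25 of 27 genes positive, 0 genes called over all genes or over the list alone, and a median of 0.39 (camera adjusted p = 1.98e-05; adjusted p = 0.648 with an estimated correlation), which was 0.23 without low tension replicate 2. Among its smallest p-values were those of Glb1 (0.96 ± 0.20), Ctsa (1.09 ± 0.30) and Tpp1 (0.56 ± 0.17), and Ctsa overlaps Pltp on the opposite strand. Cholesterol synthesis and uptake gave 1 higher gene of 24, over all genes as over the list alone, the mevalonate decarboxylase gene Mvd (0.64 ± 0.11, edgeR adjusted p = 0.0436), with Stard4 at 0.60 ± 0.16 (median 0.13, camera adjusted p = 0.0746; 0.0485 without high tension replicate 3, range 0.0485 to 0.148). Fatty acid synthesis had 0 calls among 13 genes (median 0.14, camera adjusted p = 0.129; 0.0205 without low tension replicate 2, range 0.0205 to 0.296), with Scd2 at 0.75 ± 0.22 and Acss2 at 0.58 ± 0.17. Fatty acid oxidation had 0 among 20 (median 0.07, camera adjusted p = 0.521), with Slc25a20 at -0.73 ± 0.27. At an unadjusted p under 0.05 edgeR gave 10 genes of the lipid uptake, 8 of the lysosome, 3 of the fatty acid synthesis and 2 of the oxidation list, and DESeq2 called 6, 6, 3 and 1. The macrophage marker median on these libraries was 0.94.

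Genes through which cells sense and transmit stiffness were not called as lists. Hippo pathway components gave 0 calls by edgeR among 22 genes, 7 at an unadjusted p under 0.05 and 5 by DESeq2 (median -0.064, camera adjusted p = 0.752). Wwtr1, which encodes the transcriptional coactivator TAZ, was 4.30 ± 1.16 CPM at 2 kPa and 1.63 ± 0.807 CPM at 50 kPa (-1.39 ± 0.40, edgeR adjusted p = 0.095). Its paralogue Yap1 was below 1 CPM in both groups (-0.45 ± 0.42, 0.499), and Wwc2 stood at 0.53 ± 0.14 (0.0839). Of 17 YAP and TAZ target genes, Ccdc80 and the forkhead gene Foxf2 (1.89 ± 0.35, edgeR adjusted p = 0.0481) rose, 0 fell, and 3 were higher when adjusted over the list alone, with F3, the tissue factor gene, named after its values were seen, at 2.69 ± 0.70, and at 3.56 without low tension replicate 3. The list's median was -0.16, its mean 0.16 and camera's direction higher (adjusted p = 0.624). Among 13 mechanosensitive ion channels Trpc6 fell from 2.44 ± 0.841 to 0.269 ± 0.0433 CPM (-3.17 ± 0.36), 0 rose, and over the list alone 1 was lower and 1 higher. The list's median was 0.16, its mean -0.079 and camera's direction higher (adjusted p = 0.302). Piezo1, a stretch-activated cation channel gene, was 132 ± 24.5 and 147 ± 15 CPM (0.16 ± 0.16, edgeR adjusted p = 0.525). The volume-regulated channel gene Lrrc8a stood at 0.53 ± 0.11 (0.059).

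Of 34 integrin and focal adhesion genes, the integrin beta genes Itgb3 (64.9 ± 10.5 to 34.6 ± 3.64 CPM, -0.91 ± 0.15) and Itgb8 (1.72 ± 0.940 to 0.148 ± 0.0546 CPM, -3.49 ± 0.61) fell. In this list 0 rose and 2 were lower when adjusted over the list alone (median -0.099, camera adjusted p = 0.55). Itgb3 pairs with the Itga2b product on platelets, and megakaryocyte markers on these libraries had a median of -3.19. Matrix and matrix remodelling genes had a median of 0.38 over 29 genes (camera adjusted p = 0.0458; adjusted p = 0.647 with an estimated correlation). Without low tension replicate 1 and without high tension replicate 3 the camera adjusted p was 0.194 and 0.234, with replicate number as a block 0.109 and with RLE factors 0.0535 (range 0.00267 to 0.234). The median was 0.18 without low tension replicate 2. The metalloproteinase genes Mmp13 and Mmp19 (283 ± 63.3 to 763 ± 63.2 CPM, 1.43 ± 0.19, edgeR adjusted p = 0.0348) rose, 0 genes fell, and over the list alone 2 were higher and 1 lower. Mmp12, the macrophage elastase gene, was 3789 ± 1385 and 9054 ± 1868 CPM (1.26 ± 0.36, edgeR adjusted p = 0.0962). The gelatinase gene Mmp9, also a neutrophil marker, stood at -1.17 ± 0.28 (0.0681).

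The G2 and M phase and the G1 and S phase lists were called lower by camera, each with 1 gene past the threshold. Both calls were lost with a correlation estimated per list (adjusted p = 0.739 and adjusted p = 0.751 with an estimated correlation). Low tension replicate 3 scored -0.27 and -0.29 on these lists, below high tension replicate 1 (-0.18 and -0.11) and replicate 2 (0.007 and -0.10). It lay above high tension replicate 3 (-0.60 and -0.33). All 24 G2 and M phase genes had a negative fold change. Their median was -0.59 (camera adjusted p = 0.000698; 0.053 without high tension replicate 3, range 3.08e-07 to 0.053). The proliferation marker gene Mki67 fell from 203 ± 23.7 to 126 ± 12.2 CPM (-0.69 ± 0.13, edgeR adjusted p = 0.0486), and Plk1, Cenpe and Ube2c stood at -0.96 ± 0.27, -0.76 ± 0.23 and -0.96 ± 0.29. Of 24 G1 and S phase genes, Tyms, which encodes thymidylate synthase, fell (-0.91 ± 0.16, edgeR adjusted p = 0.0444), with Mcm5 at -0.76 ± 0.25, Uhrf1 at -0.71 ± 0.23 and E2f1 at 0.37 ± 0.11. That list's median was -0.48 (camera adjusted p = 0.0144), and -0.25 without low tension replicate 2 and -0.75 without low tension replicate 3. Its camera adjusted p was 0.0759 with total counts as the scaling, 0.134 without low tension replicate 1, 0.0772 without low tension replicate 2 and 0.162 without high tension replicate 3 (range 3.32e-06 to 0.162). Adjusted over the list alone, 1 gene of each cell cycle list was lower. Markers of promyelocytes, which are dividing precursors, had a median of -2.54.

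HIF target genes outside glycolysis were called higher, with 18 of 20 positive and a median of 0.60 (camera adjusted p = 0.00106; adjusted p = 0.647 with an estimated correlation), and 0 genes passed over all genes or over the list alone. By edgeR 7 had an unadjusted p under 0.05, and DESeq2 called 6. The score of high tension replicate 3 (-0.077) lay below that of low tension replicate 1 (-0.066), and the macrophage marker median on these libraries was 0.94. Low tension replicate 2 had the lowest score, -0.65, against -0.26 in low tension replicate 3. The angiogenic factor gene Vegfa was 281 ± 32.9 CPM at 2 kPa and 428 ± 36.1 CPM at 50 kPa (0.61 ± 0.14, edgeR adjusted p = 0.065), with Rora at 1.02 ± 0.27, Ero1l at 0.99 ± 0.31 and Adm at 2.27 ± 0.84. NRF2 oxidative stress genes had a median of 0.32 over 16 genes (camera adjusted p = 0.0333; adjusted p = 0.647 with an estimated correlation; camera adjusted p = 0.194 without low tension replicate 1 and 0.186 without high tension replicate 3, range 0.00824 to 0.194). Cat, which encodes catalase, rose from 154 ± 3.63 to 212 ± 2.36 CPM (0.46 ± 0.085, edgeR adjusted p = 0.0481) on this list, 0 fell, and 5 were higher when adjusted over the list alone. Of these Mt2 stood at 1.48 ± 0.37, Srxn1 at 0.63 ± 0.16, Gclm at 0.46 ± 0.12 and Mt1, named after its values were seen, at 1.22 ± 0.37. Of 21 immediate early genes, the nuclear receptor gene Nr4a1 (-1.21 ± 0.15) and the phosphatase gene Dusp2 (-1.68 ± 0.22) fell and 0 rose, over all genes as over the list alone (median -0.15, camera adjusted p = 0.165). Unfolded protein and integrated stress response genes gave 0 calls by edgeR among 22, 5 at an unadjusted p under 0.05 and 5 by DESeq2. Adjusted over the list alone 2 were lower, the serine synthesis gene Phgdh at -1.46 ± 0.28 and Manf at -0.48 ± 0.095 (median -0.063, camera adjusted p = 0.436). The genes of the GM-CSF receptor chains, Csf2ra and Csf2rb, were at 0.075 ± 0.14 and -0.17 ± 0.20, with edgeR adjusted p-values of 0.738 and 0.609.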

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

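The GC correction and the summing of high tension replicates 1 and 2 were chosen only after the result was seen. Against 194 higher and 260 lower genes, the counts were 204 and 277 with RLE factors, 150 and 235 with upper-quartile factors, 145 and 202 with no low-count filter, 194 and 236 with limma-voom, 165 and 227 with robust fits and 187 and 254 with the GC trend removed. They moved by more than 1.5 times with total counts as the scaling (77 higher, with 257 lower), a filter of at least 5 CPM in 3 libraries (20 and 16), DESeq2 (1121 and 1251), a fold change of at least 2-fold (97 higher, with 223 lower) and the summed replicates (0 and 0 by edgeR, with 2138 genes at an unadjusted p under 0.05). With total counts the median of all genes lay at -0.16, the 2-fold threshold keeps a part of the called genes by construction, and the summed replicates leave 2 samples at 50 kPa. For the filter and DESeq2 the cause was not tested, although the filter left 262 of the 454 called genes in the test. With replicate number as a block there were 254 higher and 522 lower genes, 352 of them among the 454, and the cause was not tested. Without 1 library the higher genes numbered 0 to 255 and the lower genes 0 to 256, in fits that have fewer samples. All 454 kept their direction and an unadjusted p under 0.05 in these 6 fits, which share their libraries with the fit that called them.

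Gene lists numbered 7 higher and 13 lower by camera, 6 and 13 with RLE factors, 7 and 12 with total counts, 7 and 13 with the filter of at least 5 CPM, and 6 and 12 with the replicate block. With an estimated correlation camera called 0 and 0, and fry 0 and 0. The 20 lists had adjusted p-values of 0.647 to 0.751 with an estimated correlation, whose estimates ran from 0.057 to 0.95 against the preset 0.01, and of 0.0656 to 0.376 with fry. Without 1 library 5 to 8 lists were higher and 8 to 13 lower, the 8 without low tension replicate 3, and 11 of the 20 were called in the same direction in each of these 6 fits. Of 173 genes named in the text, 171 kept their direction under all 17 settings that gave them a value. Csf2ra, at 0.075, turned to -0.046 with total counts and -0.024 without low tension replicate 2, the lowest of the 6 fits without 1 library, of which the highest gave 0.17. Sdc1 turned from 0.36 to -0.10 without high tension replicate 3, with a highest value of 0.74 among these 6 fits. For both genes the cause was not tested. Depth limits the values of genes below 1 CPM, such as Yap1, and 214 of the 454 called genes had a mean below 5 CPM.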

Other observations

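The GC correction, the B cell against T and NK cell test, the test without low tension replicate 3 and the mixing test were chosen only after the result was seen. Further genes, chosen after their values were seen, belong to B cells, antibody-secreting cells or platelets, and no such group was tested as a list. Of 16 genes of B cells or antibody-secreting cells 8 fell by edgeR's test at 50 kPa, 0 rose and 8 were not called. Beside Igj, Mzb1, Pou2af1 and Derl3, Bhlha15 and Eaf2, genes of secretory cells, fell (-3.50 ± 0.56 and -2.72 ± 0.28), as did the BAFF receptor gene Tnfrsf13c (-3.03 ± 0.43) and Fcrla (-1.87 ± 0.22). The 8 not called lay between -0.55 and 0.58. Among them Xbp1, Prdm1 and Sdc1, which other cells express too, stood at -0.26 ± 0.17, -0.39 ± 0.20 and 0.36 ± 0.48. Of 10 platelet genes outside the preset list 7 fell, among them Mmrn1 (-3.71 ± 0.48), Selp (-3.26 ± 0.43) and Gp5 (-3.25 ± 0.43), and 0 rose. Without high tension replicate 3 Bhlha15, Mmrn1 and Selp stood at -4.20, -4.49 and -3.89. Selp shares exon sequence with genes on the opposite strand.

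Of 15 genes of the circadian clock, picked in the same way, Per1 (0.44 ± 0.075) and Per3 (1.09 ± 0.19) rose, 0 fell and 13 were not called. Dbp, a transcription factor gene that the clock drives, went from 4.16 ± 2.29 to 18.0 ± 4.50 CPM (2.11 ± 0.41, edgeR adjusted p = 0.0503), and its exons overlap Sphk2 on the opposite strand. The labels give no hour of harvest. Single called genes, picked because they were called, were those of the extracellular proteins Ecm1 (1.06 ± 0.17), Tsku (1.68 ± 0.10) and Col24a1 (1.43 ± 0.24) and of the growth factor Pdgfb (1.17 ± 0.21), which rose. Tsku had the smallest p of all genes, with 9.09 ± 0.545 CPM at 2 kPa and 29.0 ± 1.49 CPM at 50 kPa (edgeR adjusted p = 0.022). The symbol Taz in these data is tafazzin, a cardiolipin-remodelling enzyme of mitochondria on chromosome X, which rose (0.47 ± 0.073, edgeR adjusted p = 0.0369) and is not the coactivator TAZ encoded by Wwtr1 (-1.39 ± 0.40, edgeR adjusted p = 0.095).

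The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 454 called genes by edgeR and the highest other split 0, so 1 of the 10 splits gave as many, while the other splits had 25 to 2361 genes at an unadjusted p under 0.05. For gene lists the real split gave 20 calls by camera and the other splits 9 to 20, so 2 of the 10 splits gave as many. Camera at the preset correlation thus called lists in every split, so a list call does not by itself mark a difference between the stiffnesses. The other split with 20 calls sets low tension replicate 1 and high tension replicates 1 and 2 against the rest.

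The lower levels of neutrophil, B cell, megakaryocyte and basophil markers at 50 kPa had a median log2 fold change of -2.28 over their 51 tested genes, of which Mmp8, Mmp9 and Pf4 are also in another list. These 4 lists had the smallest camera adjusted p of the marker lists, so the pattern was picked from these data. A GC trend as the whole cause is argued against by the median of -2.27 after its removal. Under the other scalings the highest median was -2.27, so the pattern did not depend on which of them was used. A scaling moves all genes of a library alike, and total counts moved the median of all genes only from -0.028 to -0.16. The scaling test could therefore hardly have come out otherwise, and no conclusion is drawn from it. A lower share of every other cell type alike stays open: B cell markers lay -1.84 from T and NK cell markers in median (95% bootstrap interval over genes -3.33 to -0.029), but 11 of 12 T and NK cell markers had a mean below 5 CPM. That level was set after the values were seen, and genes of a list are not independent. S100a9 of the neutrophil list and Igj, outside the lists, were at 1676 ± 666 and 911 ± 258 CPM at 2 kPa, all 4 cell types occur in marrow, and the labels name no sort that would have removed them. It also stays open, and untested, whether fewer such cells remained on the stiff substrate, whether they expressed less of these genes, or whether the marrow plated at the start may have differed between the groups.

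Inflammatory and interferon genes, with medians of -1.35 and -1.15, might have been lower at 50 kPa only because low tension replicate 3 was activated. Without that library the medians were -0.33 and -0.19, too close to the bounds set for the test for it to decide. A GC trend as the whole cause is argued against by medians of -1.37 and -1.14 after its removal. The interferon scores were 0.21, -0.15 and 2.19 at 2 kPa and -1.31, -1.82 and 0.89 at 50 kPa, so that the replicates numbered 3 were highest in both groups. An effect of stiffness and activation of low tension replicate 3 alone cannot be told apart here. In these interferon scores low tension replicates 1 and 2 lay between the 50 kPa libraries. Each 50 kPa score was below the 2 kPa score of its own replicate number, but the labels do not say that the numbers are pairs.

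High tension replicate 3 lay between the other 50 kPa libraries and the 2 kPa libraries, at 8.06 on the first component, and RNA or reads of a low tension library mixed into it could place it there. Such a mixture needs the same share from every gene group. The shares estimated for low tension replicates 1, 2 and 3 were 30.1%, 14.5% and 20.7% from neutrophil markers and 61.9%, 44.2% and 55.3% from MHC class II genes. The smallest difference was 29.7 points (95% bootstrap interval over genes 20.2 to 39.0). The explanation stays open all the same, because the unmixed level was assumed to be that of high tension replicates 1 and 2, and ordinary variation between cultures at 50 kPa was not tested against it.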
